A study of Mus musculus with 4 samples.

How the data were processed

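H3K27 acetylation (H3K27ac), a histone mark of active promoters and enhancers, was mapped by CUT&RUN in PPO1 and PPO2, mouse lines that the labels describe as brain glioma, with 2 libraries per line and 4 in all. In CUT&RUN an antibody directs a nuclease to the mark in permeable cells and the released fragments are sequenced. Each library started from 200000 cells grown in serum-free medium with FGF and EGF, per the labels' protocols. The antibody was a polyclonal H3K27ac antibody from Active Motif, per the labels.

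The submitters' processing notes name FastQC 0.11.7, Trim Galore 0.4.2, cutadapt 1.9.1, Bowtie2 2.3.4.1, MACS2 in versions 2.1.2 and 2.1.0, and the build mm10, without saying which step used which MACS2 version. Peaks were called for each library separately, per the peak names in the deposited files. No label or note records a control library, a scaling between libraries, the handling of duplicate fragments or a filter on excluded regions. Each deposited file is a list of peaks in narrowPeak columns and holds no count table. The score deposited by the authors for each peak is the whole part of 10 times its −log10 q, tested on every peak. The deposited fold of each peak is the ratio of fragments at the summit over the peak caller's own background. The deposited −log10 p and −log10 q values are the peak caller's significance values on a −log10 scale. The least −log10 q was between 1.30 and 1.31 in the 3 longer lists and 1.46 in the fourth.

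The depth behind each peak was recovered from the deposited ratio and −log10 p, which together fix a whole number of summit fragments and a background under the peak caller's Poisson model with a pseudocount of 1. A solution within 0.001 of the deposited −log10 p was found for 99.7% and 99.9% of peaks in PPO1 replicates 1 and 2, and for 99.3% and 92.3% in PPO2 replicates 1 and 2. With p values shuffled among peaks the shares were 0.637% and 0.733%, and 1.27% and 3.52%. Median summit fragments were 12 and 14 in PPO1 replicates 1 and 2, and 12 and 64 in PPO2 replicates 1 and 2. Library totals were not used here, since the peak lists do not give them. The lowest background was 0.767, 0.966 and 1.10 fragments in PPO1 replicate 1, PPO1 replicate 2 and PPO2 replicate 1, and 0.510 in PPO2 replicate 2, where only 2 peaks had it.

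Groups were taken from the line and replicate number in the labels. The same replicate number in both lines is not described as a shared day or batch, so the lists were not paired. Overlap of each of the 6 pairs of libraries was the share of the shorter list's peaks that overlapped a peak of the longer list by at least 1 bp (bedtools 2.31.1), with exact (Clopper-Pearson) 95% intervals (scipy 1.17.1) and 100 random placements of the shorter list on the same chromosomes. The mean of the 2 within-line pairs minus the mean of the 4 between-line pairs was set against the other 2 splits of the libraries. With 3 splits the smallest exact p is 0.333. Peaks of all libraries were merged at 1 bp of overlap to count regions restricted to a line.

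Gene positions came from a RefSeq table of GRCm38.p6, the assembly of mm10, with chromosome lengths from GenomeInfoDb 1.38.1. That table gives the start and end of each gene without strand, exons or sequence. The planned window of 1 kb around transcription start sites was therefore replaced by a window of 1 kb around either annotated end of the 21887 protein-coding genes, so a peak at a gene's 3′ end is included. Peak midpoints were placed near a gene end, inside a gene or outside genes, and the planned exon and intron shares were not made. The planned test of sequence motifs was not run because the reference used here holds no genome sequence. Peaks on mitochondrial DNA and on unplaced sequences were left out of results by gene, placement and chromosome.

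A total of 24 gene lists, fixed before the data were examined, were tested per library with a two-sided Fisher's exact test against all protein-coding genes, with Benjamini-Hochberg adjustment over the 96 combinations of list and library and a threshold of 0.05. Of the names on the lists, 1 (Trac) was not matched. Genes with a peak in both libraries of a line and neither of the other were tested in the same way against genes with a peak in at least 1 library. Because the set of PPO2 was too small, PPO2 replicate 1 against both PPO1 libraries was also tested, and adjusted over its own 24 lists. Peaks within 12 kb were stitched into domains, ranked by summed peak length, and the first 100 were compared. Peaks per chromosome were compared between lines by Fisher's exact test on pooled peaks with Benjamini-Hochberg adjustment over 21 chromosomes. A chromosome was called where both libraries of a line lay on the same side of both libraries of the other. These tests describe the libraries, since genes and peaks are not replicates. Intervals cover counting error only.

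Named genes followed a fixed rule: Pten and Trp53, the genes with a peak at an end in all libraries, the first 10 per line-restricted set by mean score percentile within libraries, and up to 4 members of each list with a peak and 4 without. The first 10 genes of the 3 longer lists were added after the data were seen. The tests were checked on simulated data. Simulated pileups were recovered in 100% of 500 cases per library. They were drawn from the same range for every library, which ended below the median of 64 summit fragments in PPO2 replicate 2. Lists were also drawn with an odds ratio of 4, with 240 lists per library. Of these, 65%, 71.2% and 69.6% passed for PPO1 replicate 1, PPO1 replicate 2 and PPO2 replicate 1. For PPO2 replicate 2 0.833% passed, with the simulated share of genes with a peak set above the observed share. Unchanged lists passed in at most 0.833%. The simulated lists were adjusted within each library, not over the 96 combinations of the real test. The shares that passed can therefore overstate the power of that test.

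The alternatives fixed before the data were examined were a gene-end window of 2.5 kb, the nearest gene within 50 kb, the better-scored 50% of each list, lists as long as the shortest, reciprocal overlap, the Jaccard index, a background of genes with a peak, merging within 500 bp, other stitching settings, a replicate block and leaving out each library. Equal lists of the 3 longer libraries, and lists without sites called in PPO2 replicate 2, were added after the data were seen. Tables used pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, figures matplotlib 3.10.9, and the Reactome sets were those installed with fgsea 1.28.0.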

Results

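H3K27ac CUT&RUN peaks were available for 4 libraries, 2 from each of the mouse glioma lines PPO1 and PPO2. The series title places the lines in a study of how transit-amplifying lineage states bear on glioma formation after loss of PTEN and P53. The labels do not say how PPO1 differs from PPO2. PPO1 replicates 1 and 2 had 5652 and 13095 peaks, which covered 2372 and 6548 kb. PPO2 replicate 1 had 7067 peaks over 3067 kb, and PPO2 replicate 2 had 142 peaks over 80.9 kb. Median peak width was between 366 and 426 bp, and the median fold over background was 5.09, 4.85, 5.30 and 6.04 in the same order. Of the 142 peaks of PPO2 replicate 2, 26.1% lay on mitochondrial DNA or unplaced sequences, against 0.814%, 0.336% and 0.764% in the other lists. Comparisons that need both PPO2 libraries rest on this short list.

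Pten and Trp53, the tumour suppressors named in the title, both carried a peak at a gene end in each PPO1 library and in neither PPO2 library. PPO2 replicate 2 had a peak at an end of only 7 genes (0.0320%), so its lack of one says little. The contrast therefore rests on PPO2 replicate 1. At Pten (chromosome 19, 32757577 to 32826160, mm10), the PPO1 replicate 1 peak spanned 32757855 to 32758260 with a fold of 4.67 and 13 summit fragments. Another PPO1 replicate 1 peak, over 1 kb outside the gene, spanned 32756220 to 32756454 (fold 5.35). The PPO1 replicate 2 peak spanned 32756612 to 32757194 with a fold of 3.94 and 16 fragments and overlapped neither. At Trp53 (chromosome 11, 69580348 to 69591873), the peaks spanned 69579991 to 69580237 in PPO1 replicate 1 (fold 4.42, 14 fragments) and 69580418 to 69581379 in PPO1 replicate 2 (fold 4.31, 19 fragments), which do not overlap. Wrap53 (69561754 to 69580250) ends beside these peaks, so they cannot be assigned to Trp53 alone. The Pten peaks stood at the 44.7 and 35.8 percentiles of their lists by score and the Trp53 peaks at the 42.3 and 58.0 percentiles. Among the better-scored 50% of each list Pten kept a peak in 0 libraries and Trp53 in 1, with equal lists of the 3 longer libraries Pten did in 1, and with peaks assigned to the nearest gene Trp53 did in 1. A peak at a gene end does not test a deletion elsewhere in the gene. Of the 3115 genes with a peak in both PPO1 libraries, 36.3% had none in PPO2 replicate 1.

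**Figure D1:**
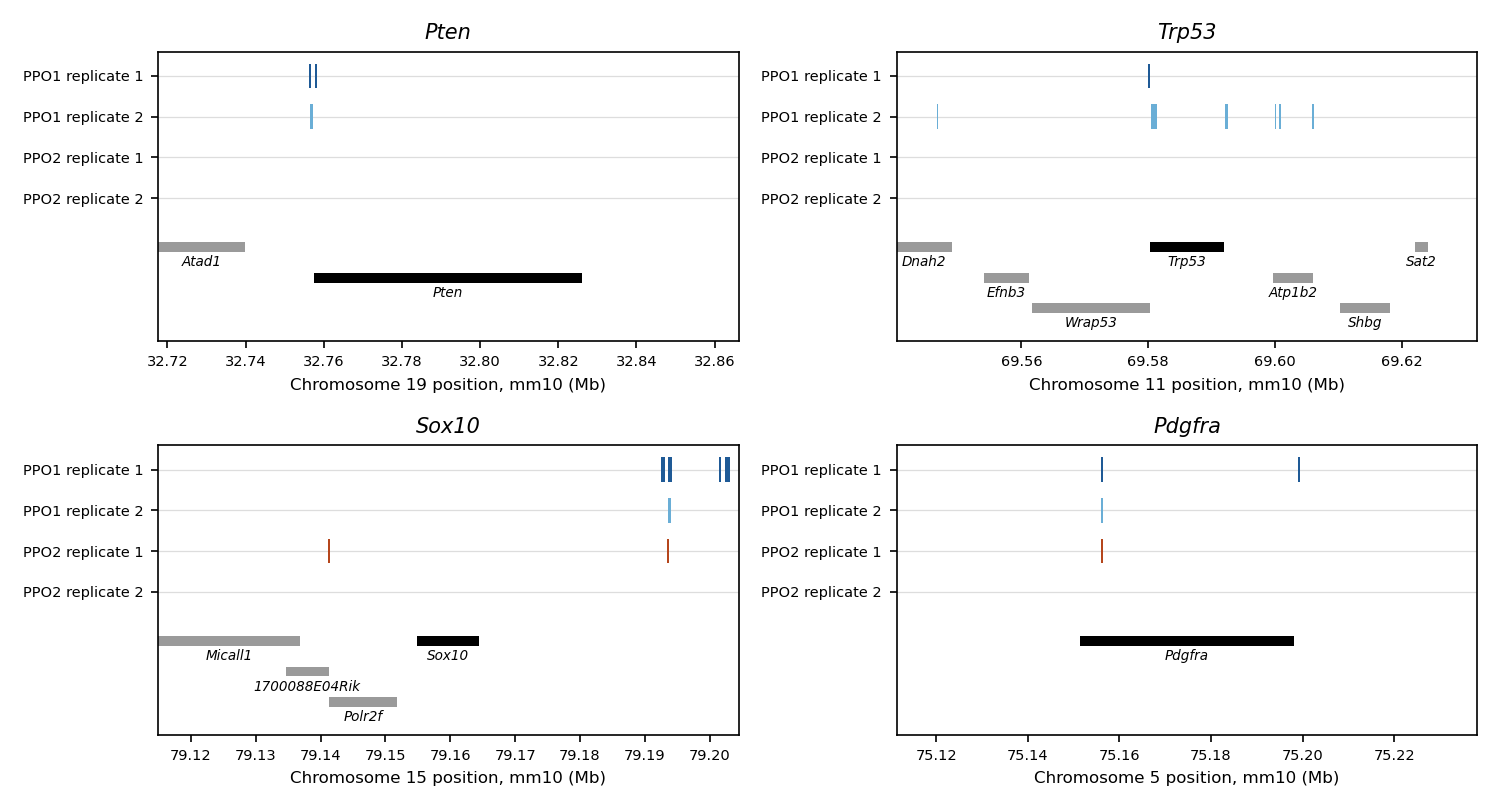
Peaks of each library (coloured bars, 1 line per library) and annotated protein-coding genes (grey and black bars) around Pten, Trp53, Sox10 and Pdgfra, with mm10 position in Mb on the horizontal axis. Pten and Trp53 have peaks at a gene end in both PPO1 libraries and in no PPO2 library, where PPO2 replicate 2 has them at only 7 genes. Pdgfra has a peak inside the gene in the 3 longer lists. Sox10 has a peak between 29.2 and 29.4 kb from its end in the same lists.

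Whether libraries of a line resembled each other more than libraries of different lines was asked from the overlap of their peaks. The PPO1 libraries shared 69.6% of the shorter list (95% interval 68.4 to 70.8%, 3935 of 5652 peaks). PPO1 replicate 1 shared 41.9% (40.6 to 43.2%) and PPO1 replicate 2 shared 49.2% (48.1 to 50.4%) with PPO2 replicate 1. Nearly the whole short list of PPO2 replicate 2 recurred in every other library, at 91.5%, 91.5% and 92.3% of its 142 peaks, whichever the line. Random placements gave medians of 0 to 0.499%. The mean within lines was 80.9% and between lines 68.5%, a difference of 12.4 points that was smaller than the spread of the 2 within-line shares (SD 16.0 points). That SD rests on 69.6% of 5652 peaks and 92.3% of 142, so it does not measure the variation between replicates alone. Both means hold pairs with the short list. The other splits gave −8.96 and −3.43 points, and with 3 splits the smallest exact p is 0.333. Without PPO2 replicate 1 the difference turned to −21.9 points, without each of the others it was 21.9 to 25.5 points, and with every list cut to the length of the shortest it was 0.352 points. The −21.9 points set the 69.6% of the PPO1 pair against the short list's 91.5% with each PPO1 library. That sign follows from the short list and says nothing of the lines. The values without PPO1 replicate 1 or without PPO1 replicate 2 also say nothing of the lines. Their only within-line share is the 92.3% of the short list. Only the value without PPO2 replicate 2 leaves the short list out. With the 3 longer lists at 5652 peaks each, the PPO1 pair shared 47.2% (45.8 to 48.5%), against 37.3% and 34.7% between lines.

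Merging all peaks gave 17720 regions. Both PPO1 libraries and no PPO2 library had a peak in 1900 regions, both PPO2 libraries and no PPO1 library in 3, and all 4 libraries in 117. Of the 3917 regions with a peak in both PPO1 libraries, 2016 (51.5%) also had one in PPO2 replicate 1, and 3136 regions had a peak in PPO2 replicate 1 and in no PPO1 library. The longest list, PPO1 replicate 2, alone held 7500 regions (42.3%). The other splits gave 1500 regions for PPO1 replicate 2 with PPO2 replicate 1 and 399 for PPO1 replicate 1 with PPO2 replicate 1, and their partner sets held 1 each. The PPO1 count was 9489 without PPO1 replicate 1, 3283 without PPO1 replicate 2 and 3772 without PPO2 replicate 1. The PPO2 count was 6 without PPO1 replicate 1, 8 without PPO2 replicate 1 and 3136 without PPO2 replicate 2.

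Most peaks of the 3 longer lists lay at genes. The share with a midpoint within 1 kb of either end of a protein-coding gene was 55.2% (53.9 to 56.5%) in PPO1 replicate 1, 48.7% (47.8 to 49.5%) in PPO1 replicate 2 and 60.8% (59.6 to 61.9%) in PPO2 replicate 1. Such stretches make up 2.91% of the assembled genome. A further 25.4%, 30.5% and 18.2% of peaks lay inside genes, against 36.3% of the genome. Of the 105 peaks of PPO2 replicate 2 on assembled chromosomes only 5.71% (2.13 to 12%) lay near a gene end and 75.2% lay outside genes. The 142 best-scored peaks of PPO1 replicate 1, PPO1 replicate 2 and PPO2 replicate 1 were also rarely at gene ends, at 14.2%, 17.1% and 3.92% of those on assembled chromosomes.

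**Figure D2:**
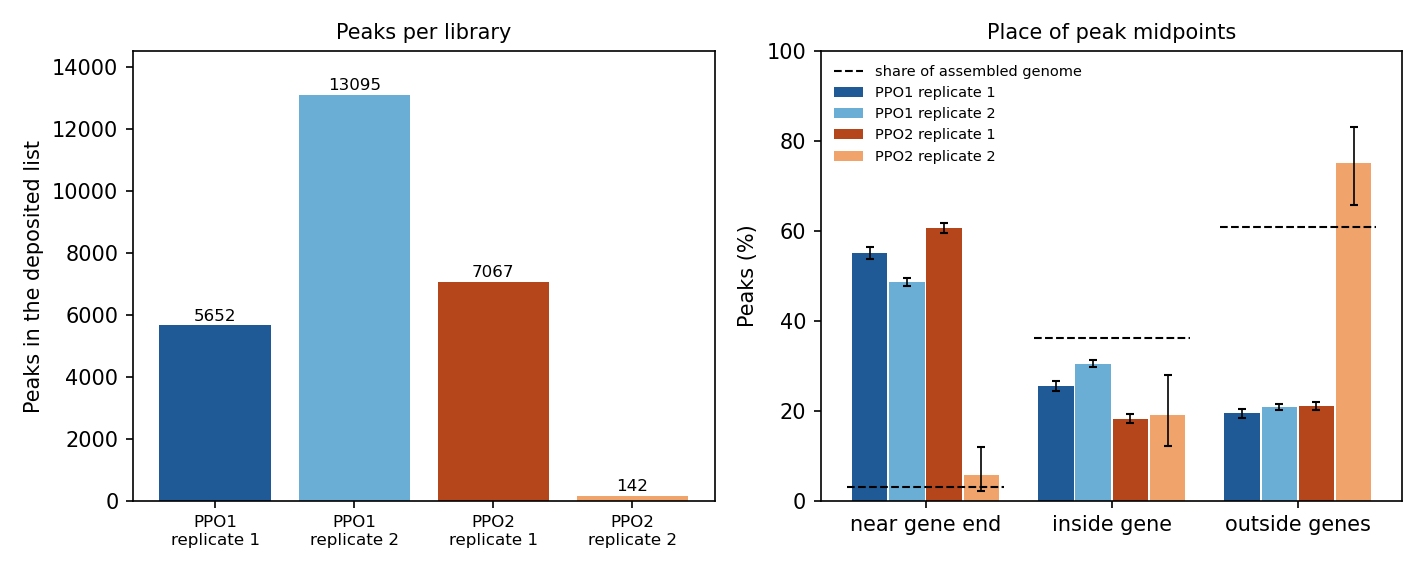
Left, the number of peaks in each library's list. Right, the percentage of peak midpoints near a gene end, inside a gene or outside genes, with exact 95% intervals as error bars and the share of the assembled genome as dashed lines. PPO2 replicate 2 has 142 peaks, and 75.2% of its 105 peaks on assembled chromosomes lie outside genes.

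Of 21887 protein-coding genes, 3656 (16.7%) had a peak at an end in PPO1 replicate 1, 6985 (31.9%) in PPO1 replicate 2, 5028 (23.0%) in PPO2 replicate 1 and 7 in PPO2 replicate 2. Genes with a peak in all 4 libraries were Lars2, a mitochondrial leucyl-tRNA synthetase, Dcp1a, an mRNA decapping factor, and Uhrf2, a ubiquitin ligase. Which genes these are rests on the 7 of PPO2 replicate 2. Dcp1a and Uhrf2 stood at only the 5.63 and 1.41 percentiles by score there. The Lars2 peak (gene at chromosome 9, 123366927 to 123462675) had folds of 16.0, 19.8, 23.7 and 14.1. A total of 1984 genes had a peak in all 3 longer lists. First among them by score were Wls, which carries Wnt proteins to the cell surface (folds 29.5, 22 and 33.6), Lars2, Hjurp, the chaperone of the centromeric histone CENP-A (7.73, 5.60 and 8.02), Ate1 and Gm4275, Anapc13, a subunit of the anaphase-promoting complex (7.11, 8.04 and 10.2), Cep63, Efcab2, Gm32584 and Rpl5, a ribosomal protein (9.21, 7.96 and 8.68). Anapc13 and Cep63 shared their peak, as did Ate1 and Gm4275.

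Proliferation genes carried peaks more often than other genes in PPO1 replicate 2, with 24 of 26 cell cycle genes (92.3%, other genes 31.8%, adjusted p = 1.82e-08, Fisher's exact test). By the same exact test PPO2 replicate 1 had 12 of 26 (adjusted p = 0.0566) and PPO1 replicate 1 had 8 (adjusted p = 0.188), neither past the threshold. With 13 of 26, PPO2 replicate 1 passed Fisher's exact test under the 2.5 kb window (adjusted p = 0.0494) and with peaks assigned to the nearest gene within 50 kb (adjusted p = 0.0388, over all alternatives 0.0388 to 1). Mcm5, a subunit of the replicative helicase, had folds of 8.48, 7.35 and 5.51 in PPO1 replicate 1, PPO1 replicate 2 and PPO2 replicate 1. Aurka, a mitotic kinase, had 5.63, 4.82 and 6.24, Kif11, a spindle motor, 4.03, 5.83 and 6.12, and Rrm2, a ribonucleotide reductase subunit, 4.18, 4.52 and 6.18. Bub1 and Bub1b, of the spindle checkpoint, had no peak in any library. Histone genes had peaks more often than other genes in all 3 longer lists, at 12, 15 and 13 of 24 (Fisher's exact test, adjusted p = 0.00412, 0.0278 and 0.0158), among them H3c1, H4c1, H2ac6 and H2bc4. These genes are clustered and near-identical, so their peaks are not independent and fragments can map to more than 1 copy. Housekeeping genes passed in PPO2 replicate 1 (15 of 25, 60%, other genes 22.9%, Fisher's exact test, adjusted p = 0.00243), with 9 and 14 of 25 in the PPO1 libraries (adjusted p = 0.116 and 0.0946). With peaks assigned to the nearest gene within 50 kb they also passed Fisher's exact test in both PPO1 libraries (12 and 18 of 25, adjusted p = 0.0127 and 0.00781, over all alternatives 0.0127 to 1 and 0.00781 to 0.853). Ppia had folds of 5.95, 6.59 and 6.68 and Rps6 of 6.79, 5.58 and 7.85, while Gapdh and Ldha had no peak.

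Immediate early and Hippo pathway genes passed in PPO1 replicate 2. Neither call stayed with the better-scored 50% of each list, and the immediate early call also ended with equal lists of the 3 longer libraries. AP-1 and immediate early genes had peaks at 3, 15 and 7 of 24 members in PPO1 replicate 1, PPO1 replicate 2 and PPO2 replicate 1 (PPO1 replicate 2 adjusted p = 0.0278, Fisher's exact test), and Hippo, YAP and TEAD genes at 5, 14 and 4 of 21 (PPO1 replicate 2 adjusted p = 0.0197). With peaks assigned to the nearest gene within 50 kb, Hippo genes also passed Fisher's exact test in PPO1 replicate 1 (11 of 21, 52.4%, adjusted p = 0.010, over all alternatives 0.010 to 1) and AP-1 genes in PPO2 replicate 1 (13 of 24, adjusted p = 0.0227, over all alternatives 0.0227 to 1). The AP-1 subunit gene Fosl2 had folds of 5.80, 5.4 and 7.55 and Junb of 3.82, 4.21 and 4.1. Lats2, a kinase that restrains YAP, had 5.64, 6.11 and 5.63, and Amotl2 and Fjx1 also had peaks in all 3. Notch pathway genes had peaks at 2, 7 and 5 of 23 members, with Maml1 in all 3 and none at Notch1 or Jag1. Sonic hedgehog genes had 4, 7 and 4 of 13, with Gas1 and Smo in all 3 and none at Gli1 or Ptch2. Neither list passed in any library.

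Lineage lists did not pass within 1 kb of gene ends in any library. Oligodendrocyte progenitor genes had peaks at 3, 6 and 3 of 25 members, among them Olig1, a transcription factor of that lineage (PPO1 replicate 2 fold 4.69, PPO2 replicate 1 fold 4.14), with none at Olig2, Sox10, Sox8 or Cspg4. Differentiated oligodendrocyte genes had 3, 3 and 3 of 20, with none at Mbp, Plp1, Mog or Mag. Astrocyte and radial glia genes had 3, 9 and 3 of 26, among them the gliogenic factor Sox9 (4.73 and 4.84 in PPO1 replicate 2 and PPO2 replicate 1) and Vim, an intermediate filament (4.38 and 4.27 in the PPO1 libraries), with none at Gfap, Aqp4 or Slc1a3. Transit-amplifying and neural progenitor genes had 2, 7 and 5 of 24. Of these the stem cell factor Sox2 had folds of 3.25, 2.38 and 4.96, and the EGF receptor gene Egfr had 5.04 in PPO1 replicate 2 and 4.80 in PPO2 replicate 1, with none at Ascl1, Dlx1, Dlx2 or Dlx5. Neuron genes had 0, 2 and 3 of 22. With the 2.5 kb window they passed for fewer in PPO1 replicate 2 (2 of 22, Fisher's exact test, adjusted p = 0.0494, over all alternatives 0.0494 to 0.853). Mesenchymal glioma genes had 4, 10 and 2 of 25, with Fosl2 and Stat3 in all 3 longer lists. Glioma driver genes had 8, 16 and 7 of 28 (adjusted p = 0.316, 0.0507 and 1, Fisher's exact test). The G1 kinase gene Cdk4 had folds of 5.58, 5.08 and 8.45, Ezh2, the H3K27 methyltransferase, 4.87, 4.95 and 6.63, and Atrx, a chromatin remodeller, 7.98, 5.60 and 5.71, with none at Pdgfb, Met, Fgfr3 or Myc. Brain region factors had 2, 6 and 1 of 26.

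Hox genes, which pattern the body axis behind the forebrain, had peaks less often than other genes in all 3 longer lists, at 0, 4 and 0 of 39 (adjusted p = 0.0211, 0.0278 and 0.00243, Fisher's exact test). The 4 were Hoxa3, Hoxa4, Hoxa5 and Hoxa6 in PPO1 replicate 2. Hox genes lie in a few tight clusters and can share peaks, as Hoxa5 and Hoxa6 did, so the members are not independent and the test overstates the evidence. Endothelial and pericyte genes had 0, 0 and 3 of 20, past the threshold for fewer in PPO1 replicate 2 (adjusted p = 0.0158, Fisher's exact test), and the 3 in PPO2 replicate 1 (15%, adjusted p = 0.968) were Sox17, Kcnj8 and Abcc9. Microglia and macrophage genes had 0, 1 and 1 of 20, fibroblast and meninges genes 0, 1 and 0 of 17, and T cell genes 0 of 14 in each. The control tissues had 0, 1 and 0 of 15 for muscle, 0, 1 and 0 of 15 for liver and 1, 1 and 1 of 16 for the germ line, where the gene was Gdf9. In PPO1 replicate 2 T cell genes passed for fewer with the 2.5 kb window and the 3 control tissues with the nearest gene (Fisher's exact test, adjusted p = 0.0328, 0.0135, 0.0135 and 0.0453, each up to 1 over all alternatives). In PPO2 replicate 2 no member of any list had a peak at an end, and 0 lists passed at an unadjusted p of 0.05.

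In all, 1 list passed for more peaks in PPO1 replicate 1, 4 in PPO1 replicate 2 and 2 in PPO2 replicate 1, and 1, 2 and 1 for fewer. Against genes with a peak in at least 1 library no list passed (lowest adjusted p = 0.374, Fisher's exact test). Of the 8670 genes in that background 6985 had a peak in PPO1 replicate 2, and only 4 of 39 Hox genes were in it. Calls lost there in PPO1 replicate 2 or for fewer peaks therefore say little. With the better-scored 50% of each list only the cell cycle call of PPO1 replicate 2 and the histone calls of PPO1 replicate 2 and PPO2 replicate 1 stayed. With equal lists of the 3 longer libraries the AP-1, Hox, and endothelial and pericyte calls of PPO1 replicate 2 ended (Fisher's exact test, adjusted p = 0.865, 0.112 and 0.141, over all alternatives 2.44e-05 to 1, 0.00542 to 1 and 0.00296 to 0.374), and with peaks assigned to the nearest gene within 50 kb the histone calls ended in Fisher's exact test against all genes (0.0653, 0.102 and 0.0958, over all alternatives 0.000121 to 1).

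**Figure D3:**
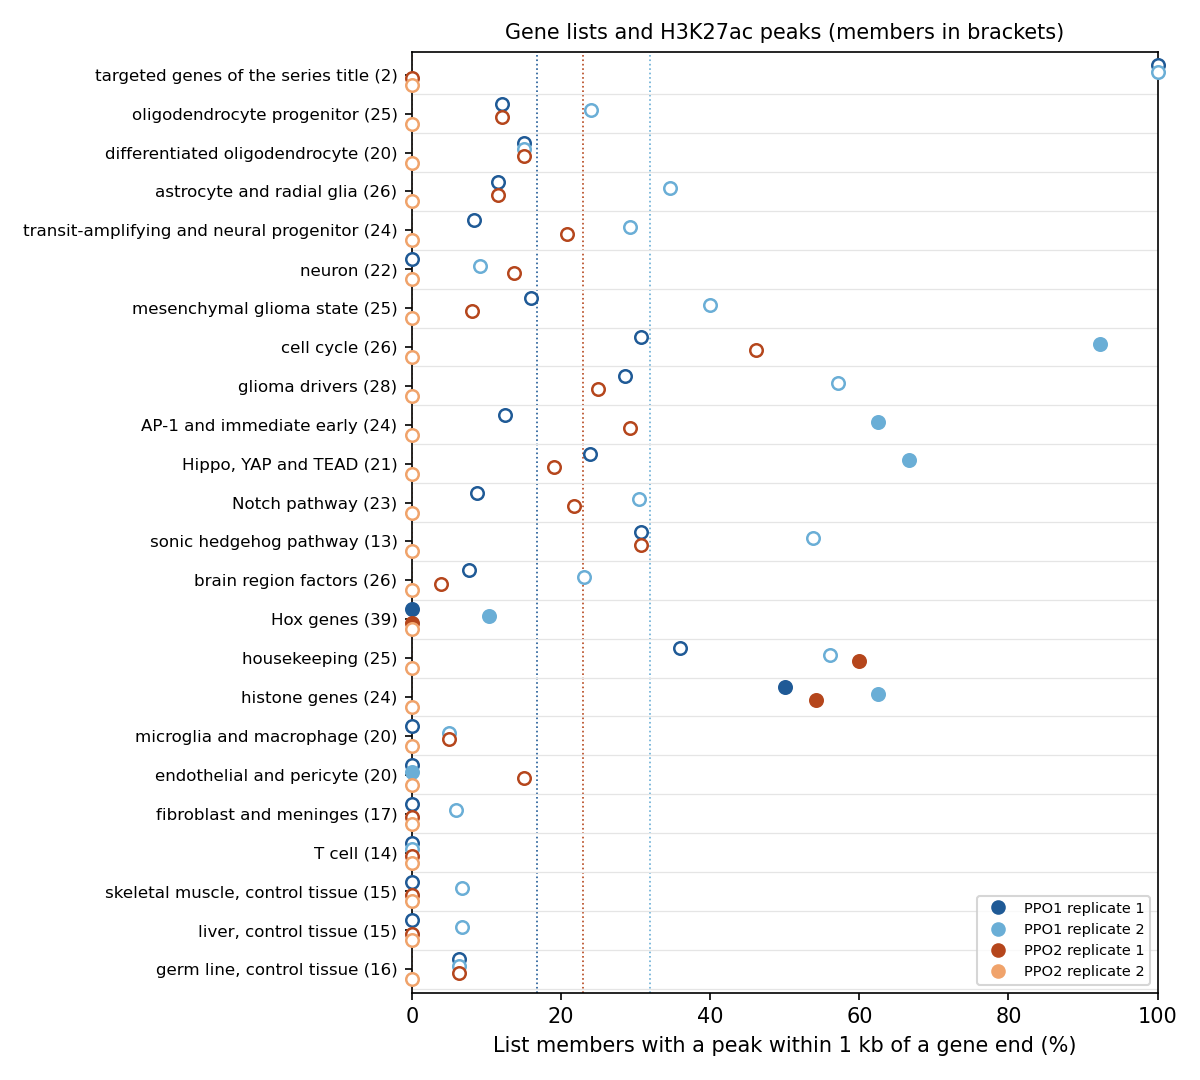
Percentage of the members of each gene list with a peak within 1 kb of a gene end, 1 point per library, with list sizes in brackets and filled points past the adjusted threshold. Dotted lines give the share of all protein-coding genes (16.7%, 31.9% and 23.0% in the 3 longer lists). Cell cycle genes stand at 92.3% in PPO1 replicate 2.

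Genes restricted to a line were asked about next. A peak in both PPO1 libraries and no PPO2 library was found at 1131 genes, and the reverse at 0 genes. First by score in the PPO1 set were Zfp619 (folds 12.7 and 11.3), Csnk1d, casein kinase 1 delta (8.67 and 10.3), Cwc22, a splicing factor, Polr2a, the catalytic subunit of RNA polymerase II (6.48 and 6.97), Slc35g3, Itprip (7.70 and 8.11), Hspb6, Proser3, Sqstm1, the autophagy receptor p62 (6.68 and 6.07), and Chkb, a choline kinase (9.33 and 7.16). Polr2a shared its peak with Slc35g3, and Hspb6 with Proser3. PPO2 replicate 1 had a peak at 1144 genes with none in PPO1, first among them Marchf8, a membrane ubiquitin ligase (10.8), Gm51572, Fcgr3, an Fc receptor (6.04), 1700088E04Rik, Polr2f, Unc5b, a netrin receptor (9.25), Kdm1b, an H3K4 demethylase (9.67), Tpmt, Gtf2h5, a TFIIH subunit, and Serac1. Kdm1b shared its peak with Tpmt, Gtf2h5 with Serac1 and 1700088E04Rik with Polr2f. These values rest on 1 library.

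No gene list passed among the PPO1 genes, where the lowest adjusted p was 0.816, for Pten and Trp53 (unadjusted p = 0.0170, Fisher's exact test, 2 of 2 genes). The PPO1 set held Glul, Hes1 and Vim of the astrocyte list, Aurkb, Ccnb2 and Foxm1 of the cell cycle list, Cebpd (5.41 and 5.95) and Lgals1 (4.92 and 4.46) of the mesenchymal list, and Lats1 and Wwtr1 of the Hippo list. The housekeeping genes Actb and Rpl13a were in it too (2 of 21, 9.52%, other genes 13.1%). No list passed among the genes of PPO2 replicate 1 alone either, where the endothelial and pericyte list, with Sox17 (fold 4.46) and the pericyte markers Kcnj8 (5.23) and Abcc9 (3.81), which lie close together on chromosome 6, had an adjusted p of 0.0550 (unadjusted p = 0.00229, Fisher's exact test, 3 of 3 genes with a peak in any library). With the 2.5 kb window this list passed (Fisher's exact test, adjusted p = 0.0462, over all alternatives 0.0462 to 1). That set also held the neuronal genes Nefl and Syt1, the Notch pathway genes Hey2, Heyl and Lfng, and Sox1 and Sox11. It held the housekeeping genes Eno1, Hsp90ab1, Pgk1, Rps18, Tbp and Ubc as well. These were 6 of 21 (28.6%, other genes 13.2%, Fisher's exact test, unadjusted p = 0.0490, adjusted p = 0.515). Of all genes with a peak in at least 1 library, 13.2% were in that set. With equal lists of the 3 longer libraries 687 of the 1131 PPO1 genes and 911 of the 1144 PPO2 replicate 1 genes stayed in their sets, and with the better-scored 50% of each list 446 and 505 did. Leaving out PPO1 replicate 1, PPO1 replicate 2 or PPO2 replicate 1 moved a count by over 1.5 times, to 3375 and 3112 genes for PPO1 without PPO1 replicate 1 and without PPO2 replicate 1 and 2769 for PPO2 replicate 1 without PPO1 replicate 2.

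Stitched domains were compared to describe the stretches with the most summed peak length. The first 3 in every library lay on 1 unplaced sequence, at chromosome 9 from about 3000052 to 3038283 and on mitochondrial DNA. The chromosome 9 stretch held no end of an annotated protein-coding gene, and genes on the other 2 sequences were not analysed here. All 3 recurred in the short list of PPO2 replicate 2. Mitochondrial DNA is not packaged with histones, so its peaks cannot be read as acetylation. With no control library analysed here, acetylation at the unplaced sequence and the chromosome 9 stretch cannot be told from background signal. Without sites called in PPO2 replicate 2, PPO1 replicate 1 began with chromosome 15, 98969662 to 98993669, and 79192558 to 79203157, the nearest stretch with peaks to Sox10 on that side. PPO1 replicate 2 began with chromosome 5, 103752938 to 103804522, and PPO2 replicate 1 with chromosome 6, 47654840 to 47686590, a cluster of predicted genes that includes Gm40369 and Gm36327. Of the first 100 domains, the PPO1 libraries shared 29 (20.4 to 38.9), PPO1 replicate 1 and PPO2 replicate 1 shared 30 (21.2 to 40.0), and PPO1 replicate 2 and PPO2 replicate 1 shared 21 (13.5 to 30.3), so the within-line share lay inside the intervals of the others. Without sites called in PPO2 replicate 2 the shares were 22%, 17% and 15% in the same order, and with 5 kb stitching 17%, 24% and 16%. PPO2 replicate 2 had only 82 domains and was not compared.

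Peaks on chromosomes 6, 11 and 15 took a larger share in both PPO1 libraries and those on chromosomes 1, 9 and 17 in both PPO2 libraries, past the threshold on pooled peaks. Chromosome 15 had 6.46% of the peaks of PPO1 replicate 1, against 4.14% in PPO1 replicate 2, 3.81% and 1.9% in PPO2 replicates 1 and 2, and 3.82% of the assembled length (adjusted p = 0.00121, Fisher's exact test). The replicates of PPO1 thus differed on chromosome 15 by more than PPO1 replicate 2 differed from either PPO2 library. Chromosome 11 had 9.45%, 7.75%, 7.41% and 3.81%. Chromosome 9 had 5.65%, 5.52%, 6.20% and 21%, and its call ended without PPO2 replicate 2 (adjusted p = 0.0705, Fisher's exact test). Of the chromosome 9 peaks of PPO2 replicate 2, 19 lay in 1 stretch of 38.1 kb, where the other lists had 22, 20 and 19. On pooled peaks alone 15 chromosomes passed, 6 of them with both libraries of each line on the same side. Without PPO2 replicate 2 that count was 13, and without PPO2 replicate 1 it was 1. With a library left out fewer libraries have to lie on the same side. The rule is then easier to meet, so the rise to 13 does not show more differences between the lines.

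**Figure D4:**
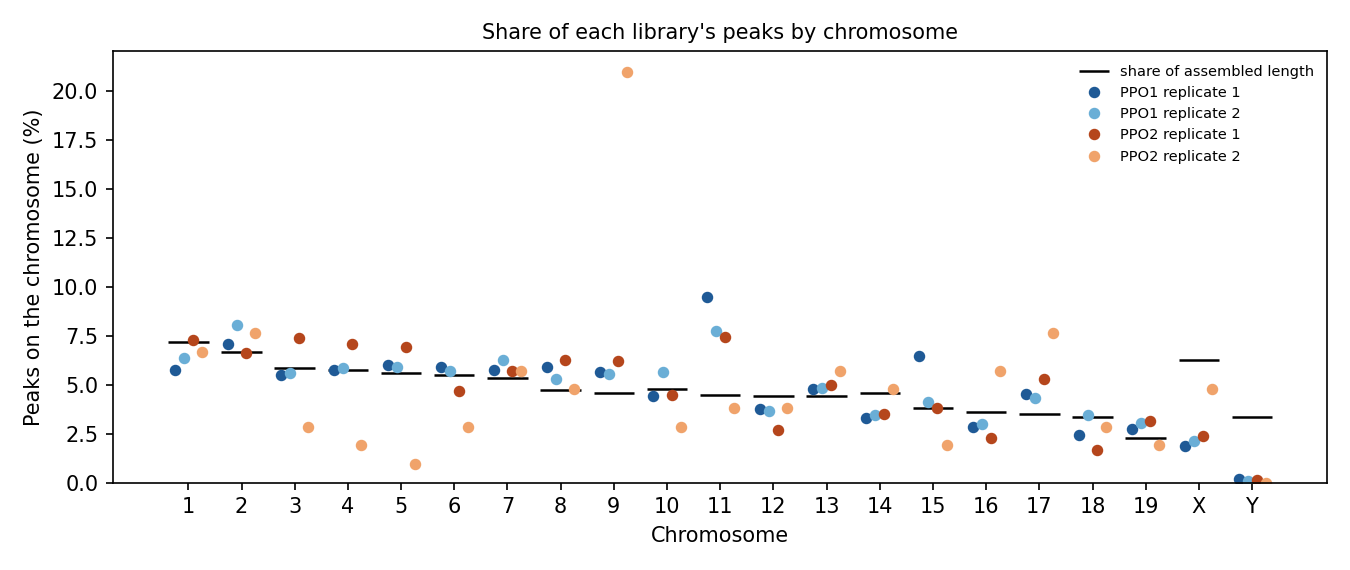
Share of each library's peaks on each chromosome (points, percent), with the chromosome's share of the assembled length as black lines. Chromosome 15 stands at 6.46% in PPO1 replicate 1, and chromosome 9 at 21% in PPO2 replicate 2, where 19 peaks lie in 1 stretch of 38.1 kb.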

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

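All tests of explanations in this part were chosen after the results were seen. Peaks outside the assembled chromosomes, which the results by gene, placement and chromosome left out, numbered more than 3, the limit that a count of 0 allows, in every library. That limit shows only that peaks were called there, since no level was set beforehand for these sequences. Peaks on mitochondrial DNA, which is not packaged with histones, cannot be read as its acetylation. Mitochondrial DNA carried 7 and 6 peaks in PPO1 replicates 1 and 2, and 5 and 7 in PPO2 replicates 1 and 2. An unplaced sequence of the build carried 33 and 33 peaks in PPO1 and 41 and 27 in PPO2, in the same order. These values were not set against an antibody-free library, which was not analysed here.

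PPO2 replicate 2 had 142 peaks where the other libraries had 5652 to 13095, and 91.5 to 92.3% of its peaks recurred in each of the others. A stricter threshold for that list is argued against, since its least −log10 q was 1.46 and the other lists would need a threshold of 18.1, 21.5 or 26.1 to shrink as far. The cell line is argued against as the cause, since the other PPO2 library had 7067 peaks, more than PPO1 replicate 1. Lower sequencing depth could account for part of the loss: at the depth ratios estimated for the short list (0.665, 0.528 and 0.313), the other lists would keep 1981, 3092 and 367 peaks, of which 104, 109 and 69 were called. These ratios are upper limits, because they rest on sites chosen for being called in the short list and on a lowest background seen at 2 peaks, and ratios of 0.25, 0.20 and 0.21 would leave as many peaks as it holds, so lower depth and weaker enrichment cannot be told apart.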

How the results depend on the processing

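Of 230 values recomputed under alternatives, 52 of those that answer a comparison moved and 1 reversed, and of the named genes and lists 25 became weaker and 4 moved. The others kept their direction and their side of the threshold, or for counts stayed within 1.5 times. Equal lists of the 3 longer libraries and lists without sites of PPO2 replicate 2 were chosen after the data were seen. Fewer peaks or libraries explain lower counts by construction, and fewer libraries make rules on both libraries of a line easier to meet. The 1 reversal, of the within-line excess without PPO2 replicate 1, follows from the high overlap of the short list with every library. For the other shifts the cause was not tested. The within-line excess of 12.4 points was 7.03 with reciprocal overlap, 2.53 with the Jaccard index, 0.352 with lists as long as the shortest, 13.5 with the better-scored 50% and 11.1 with equal lists of the 3 longer libraries. It ranged from −21.9 (without PPO2 replicate 1) to 25.5 when libraries were left out. Of these values, all but the one without PPO2 replicate 2 rest on the short list. With a replicate block it was 10.5 points. The lines share only replicate numbers, which pair nothing by the labels, and with 4 libraries the block has no test. Short lists and unknown library totals limit every count, and the planned motif alternatives were not run for lack of a genome sequence. Leaving out libraries does not apply to shares of single libraries.

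Regions restricted to PPO1 numbered 1034 with the better-scored 50%, 6 with lists as long as the shortest, and 1901 to 9489 with a library left out. Those restricted to PPO2 numbered 0 with the better-scored 50%, 2904 with equal lists of the 3 longer libraries, 0 without sites of PPO2 replicate 2, and 4 to 3136 with a library left out. Regions in every library numbered 69, 1337 with equal longer lists, and 118 to 2016. Genes restricted to PPO1 ranged from 1131 to 3375, those restricted to PPO2 from 0 to 1144, and those of PPO2 replicate 1 alone from 1144 to 2769 with a library left out. Genes restricted to PPO2 numbered 2 with the nearest gene and 1621 with equal longer lists. With the 2.5 kb window 1 list, endothelial and pericyte, passed among genes of PPO2 replicate 1 alone.

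The share of peaks near gene ends was 60.9%, 55.8% and 66.6% with the 2.5 kb window, and 58.2%, 54.0%, 66.8% and 0% with the better-scored 50%. Lists with more peaks numbered 4 in PPO1 replicate 1 and 7 in PPO1 replicate 2 with the nearest gene. With the better-scored 50% they numbered 0, 2 and 1 in PPO1 replicate 1, PPO1 replicate 2 and PPO2 replicate 1, and 0 in each against genes with a peak. Lists with fewer peaks numbered 0 in each under both of these settings. In PPO1 replicate 2 they numbered 4 with the 2.5 kb window, 5 with the nearest gene and 0 with equal longer lists. The background of genes with a peak leaves out members without one and mostly holds genes with a peak in PPO1 replicate 2. Its counts of 0 for that library and for fewer peaks therefore say little. Over the alternatives the adjusted p of cell cycle genes in PPO1 replicate 2 lay between 1.80e-08 and 0.374, of Hippo genes between 0.0196 and 0.834, and of housekeeping genes in PPO2 replicate 1 between 0.000286 and 1.

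The PPO1 libraries shared 17% of first domains with 5 kb stitching (24% and 16% for PPO1 replicates 1 and 2 with PPO2 replicate 1) and 44% of the first 50 (38% and 28%). Without sites of PPO2 replicate 2, PPO1 replicate 1 and PPO2 replicate 1 shared 17%, the PPO1 libraries 22% and the third pair 15%. Chromosomes that differed numbered 13 without those sites and 1 to 13 with a library left out. Both counts of 13 set PPO1 against PPO2 replicate 1 alone, where the same-side rule is easier to meet.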

Other observations

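The Reactome sets, the tests of nearby peaks beyond the fixed lists and all tests of explanations in this part were chosen after the results were seen. The 1984 genes with a peak at an end in all 3 longer lists were rich in genes of basic cell functions. Of 151 translation genes, 50 (33.1%) were among them against 8.90% of other genes (adjusted p = 1.25e-13, Fisher's exact test), as were 59 of 234 M phase genes (25.2%, adjusted p = 1.20e-10), 49 of 213 chromatin modifying enzymes (23.0%, adjusted p = 4.30e-08) and 34 of 125 mRNA splicing genes (27.2%, adjusted p = 1.49e-07). Rhodopsin-like receptors had 3 of 300 (1.00%, adjusted p = 1.49e-07, Fisher's exact test) and potassium channels 1 of 98 (adjusted p = 0.0117). In all, 213 of 956 sets passed the adjusted threshold for more members and 9 for fewer. Among genes restricted to PPO1, 0 of 684 sets passed Fisher's exact test (lowest adjusted p = 0.959, 24 at an unadjusted p of 0.05), and among those of PPO2 replicate 1 alone also 0 (lowest adjusted p = 0.0835, 30 unadjusted). With peaks assigned to the nearest gene within 50 kb, genes of PPO2 replicate 1 alone held 26 of 88 members of GPCR ligand binding (29.5%, other genes 13.2%, adjusted p = 0.0202, Fisher's exact test) and 41 of 162 of GPCR downstream signaling (25.3%, adjusted p = 0.0202), overlapping sets that rest on 1 library.

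Peaks away from gene ends were found at some glial and glioma genes, among them Pdgfra, Sox10 and Myc. Pdgfra, the growth factor receptor of oligodendrocyte progenitors (chromosome 5, 75151322 to 75198206), had a peak inside the gene in all 3 longer lists, at 75156052 to 75156288 in PPO1 replicate 1 (fold 6.74), with folds of 6.43 in PPO1 replicate 2 and 4.54 in PPO2 replicate 1. Sox10, a transcription factor of that lineage (chromosome 15, 79154913 to 79164490), had a peak between 29.2 and 29.4 kb from its end in all 3 (folds 4.80, 4.95 and 4.55), and Myc a peak between 47.7 and 48.3 kb away (3.31, 4.02 and 4.44). Only protein-coding genes were considered, so these peaks may lie nearer to a non-coding gene and cannot be assigned to Sox10 or Myc alone. The planned assignment of peaks to the nearest gene within 50 kb also counts peaks at gene ends. At an end, 8, 16 and 7 of 28 glioma drivers had a peak in PPO1 replicate 1, PPO1 replicate 2 and PPO2 replicate 1. Under the nearest-gene assignment, glioma drivers had 14, 21 and 13 of 28 members with a peak in the same order (adjusted p = 0.00542, 0.00291 and 0.0653, Fisher's exact test). Under the other gene-list settings none of these passed (0.0507 to 1). Astrocyte and radial glia genes passed Fisher's exact test in PPO1 replicate 2 (18 of 26, adjusted p = 0.0135) and AP-1 genes in PPO2 replicate 1 (13 of 24, adjusted p = 0.0227), and neither did under the other gene-list settings (1 in each for the astrocyte list, 0.364 to 1 for AP-1). Against 10000 random lists matched on the length of the stretches nearest to their genes, with the same nearest-gene assignment, glioma drivers passed in PPO1 replicates 1 and 2 (permutation test, adjusted p = 0.0126 and 0.00840), the astrocyte list in PPO1 replicate 2 and AP-1 genes in PPO2 replicate 1 (0.0124 each), and histone genes in the 3 longer lists (0.0123, 0.0124 and 0.0124). Housekeeping genes passed the same permutation test in the 3 longer lists (adjusted p = 0.00288, 0.00240 and 0.00288). So did cell cycle genes in PPO1 replicate 2 and PPO2 replicate 1 (0.00240 and 0.0133). AP-1 genes also passed in PPO1 replicate 2 (0.00240) and Hippo genes in PPO1 replicate 1 (0.0134). Passing was therefore not particular to glial or glioma genes.

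Oligodendrocyte progenitor genes had peaks nearby at 12, 16 and 6 of 25 members in PPO1 replicate 1, PPO1 replicate 2 and PPO2 replicate 1 (adjusted p = 0.0127, 0.0391 and 1, Fisher's exact test), whereas under the other alternatives the PPO1 values were 0.865 to 1. The stretches nearest to these genes are larger (median 72.7 against 46.4 kb). In a permutation test with 10000 random lists matched on that length, 12 members were reached at an adjusted p of 0.0283 (median 6) and 16 at 0.124 (median 11), adjusted over 72 combinations of list and library, so larger stretches are not excluded for PPO1 replicate 2, and PPO2 replicate 1 lay near the median of 7 (adjusted p = 1). At equal list lengths the counts were 12, 9 and 4, or 48%, 36% and 16% against 19.7%, 19.7% and 21.2% of other genes (Fisher's exact p = 0.00132, 0.0725 and 0.632). Bcan, Bcas1, Nkx2-2, Sox6, Sox8 and Zfp36l2, 6 of the 19 members with a nearby peak, had it in both PPO1 libraries and no PPO2 library (31.6%, other genes 13.8%, Fisher's exact p = 0.0377, not adjusted over the 24 lists), which restates the counts that singled the list out, and at gene ends 1 of 8 did (12.5%, other genes 13.0%, Fisher's exact p = 1). With only 1 PPO2 library of usable length, a difference between the lines and a difference between libraries cannot be told apart.

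Chromosome 15 held 6.46% of the peaks of PPO1 replicate 1 and 4.14% of those of PPO1 replicate 2. At 223 chromosome 15 peaks shared by the PPO1 libraries the background was higher in replicate 1 by 0.41 on the log2 scale (bootstrap 95% interval 0.37 to 0.46) and the summits by 0.35 (0.26 to 0.46), relative to other chromosomes. A property of the line is argued against, since PPO1 replicate 2 exceeded PPO2 replicate 1 by only 0.0855 (−0.04 to 0.17). Extra copies of chromosome 15 in the culture behind PPO1 replicate 1 and more acetylation there cannot be told apart: the background is the peak caller's own value at the same peaks, and background minus summit rise (0.0532, −0.05 to 0.14) lay inside the −0.10 to 0.08 of the other chromosomes. The background of PPO1 replicate 1 lay above other chromosomes in 11 of 11 stretches of 10 Mb (1.22 to 1.70 times), against 8 of 11 in PPO1 replicate 2 and 3 of 11 in PPO2 replicate 1. Shifts near this size occurred elsewhere, at −0.28 on chromosome 16 between the PPO1 libraries and at 0.35 on chromosome 16 and 0.29 on chromosome 18 for PPO1 replicate 2 against PPO2 replicate 1, and no DNA input was analysed here.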
